A study of Mus musculus with 15 samples.

How the data were processed

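Sequencing libraries came, per the labels, from total RNA isolated with TRIzol from wild-type BMDMs after 9 h of stimulation, and were made with a TruSeq stranded mRNA kit. The authors deposited a gene table with estimated counts, of which 5.477 to 6.514% per library were not whole numbers. The submitters' processing notes name Trim Galore (version not given), STAR 2.7, RSEM 1.3.1 and DESeq2 (version not given). The genome build and the strand setting of the counting are not given in the sources used here. Of 55573 gene identifiers, 55180 matched, version included, the GENCODE M21 annotation of GRCm38 used here for gene types and positions. The 92 spike-in entries held no counts and were removed. The 122 duplicated symbols were kept as separate genes by identifier.

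Counts were rounded to whole numbers and analysed in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, scaled with TMM and fitted with the edgeR quasi-likelihood model, with 1 coefficient for each of the 5 groups, 10 residual and 8.39 prior degrees of freedom. Each comparison was tested with the quasi-likelihood F test, and p was adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the limit. The interaction was the contrast of LPS+CS minus LPS minus CS plus media. Standard errors were derived from the fitted log2 fold change and its F statistic. For genes without counts in a group, folds were given against a floor of 3 counts, and for 1 to 3 counts as a ratio with an exact counting interval.

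Changes were described through 34 fixed gene lists: inflammatory cytokines and chemokines, NF-kB feedback regulators, interferon-stimulated genes, inducible effector enzymes, alternative activation markers, antigen presentation, amino acid stress response, endoplasmic reticulum chaperones, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, mitochondrial dynamics and mitophagy, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, liver X receptor targets, lysosome and autophagy, FOXO-associated genes, mTOR pathway components, ribosomal proteins, ribosome biogenesis, cell cycle, p53-associated genes, oxidative stress response, hypoxia-associated genes, heat shock, cell death machinery, immediate early genes, macrophage identity, neutrophil markers, lymphocyte markers, dendritic cell markers, stromal markers, and erythroid and mast cell markers. The 31 lists with at least 5 tested members were tested in 5 comparisons with camera of limma 3.58.1 at the preset correlation of 0.01, and p was adjusted over the 155 tests. Camera with a correlation estimated for each list and fry were run beside it. Members were also counted after adjustment over the list alone.

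Named genes followed a rule. For each of the 5 main comparisons these were the 4 largest rises and 4 largest falls among genes past the test with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out predicted genes and pseudogenes. The rule added up to 4 members of each described list with the smallest adjusted p, and the fixed genes Tnf, Il1b, Il6, Il10, Ifnb1, Nos2, Acod1, Ddit3, Trib3, Gdf15, Hmgcs1, Txnip, Mtor, Rictor, Rptor, Ninj1 and Gsdmd. The other comparisons had 2 rises and 2 falls each. For the interaction no rule on overlap was applied. The lists, the comparisons, the rule and the alternatives were fixed before the data were examined, except where stated.

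Alternatives were RLE factors, upper quartile factors, library totals only (added after the scaling factors were seen to differ between the groups), DESeq2 1.42.0, limma-voom, a block for the replicate number, a fit of only the compared groups, no filter on low counts, a stricter filter of 5 CPM in 3 samples, a limit of 1 on the absolute log2 fold change, and leaving out each sample. Correlations of log2 fold changes across genes were computed for 4 pairs of comparisons without a common library. Regrouping used all 10 splits of the 6 samples of a comparison, and all 100 splits for the interaction.

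Near-identical copies of 200 named genes were searched among the transcripts of the reference annotation, at 99% identity over at least 250 nt, limits set after the values were seen. Such a stretch was found for 38 genes, and for 8 of them a copy held at least 10% of the summed counts. Bcl2a1d held 40.3% of the counts summed with Bcl2a1b. For genes with such copies, changes were recomputed with the counts of the copies added.

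The procedure was tested on simulated data with 200 changed genes. Apart from these genes all groups shared a common mean profile, whereas the real comparisons called 33 to 85.7% of tested genes. The simulation thus held no large shift in composition between groups, and its rates may not hold for the real comparisons. For CS against media 71.6, 83.6 and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 8.29% false calls. The interaction gave 53.7, 73.1 and 83.3% with 6.04% false calls, and LPS+CS+Torin against LPS+CS gave 65.7, 89.6 and 90.9% with 4.09%. Comparisons without simulated change gave 0, 0 and 2 calls.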

Results

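The series measured mRNA by RNA sequencing in mouse bone marrow-derived macrophages (BMDMs), macrophages grown in culture from bone marrow progenitors. The 15 libraries, all from wild-type cells, fell into 5 groups of 3: media, LPS, CS, LPS+CS and LPS+CS+Torin, each at 9 h. LPS is lipopolysaccharide, an outer membrane component of Gram-negative bacteria that macrophages sense through Toll-like receptor 4. The labels do not expand CS, and it is used here only as the name of a stimulus. Torin, whose number the labels do not give, is an ATP-competitive inhibitor of the kinase mTOR; no group received Torin without LPS and CS. The title of the series names innate immune and metabolic signalling, damaged mitochondria and the cell membrane, so genes of these processes are followed below.

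The deposited table held estimated counts for 55573 genes. Library totals, in 1e6 counts, were 34.91 to 65.17 in media, 46.02 to 61.65 with LPS, 32.59 to 55.65 with CS, 50.6 to 65.31 with LPS+CS and 49.16 to 56.54 with LPS+CS+Torin. After a filter on low counts 15496 genes were tested, with a common biological coefficient of variation of 4.49%. The labels do not say whether the 3 replicates of a group came from separate animals or cultures, so p-values measure only the spread between these libraries. Levels below are TMM-scaled counts per 1e6 counts (CPM), mean ± SD of n = 3, and changes are log2 fold changes ± SE. Adjusted p is from the edgeR quasi-likelihood test with Benjamini-Hochberg correction unless another test is named. The first principal component, 76.3% of the variance, placed the 6 libraries without LPS at -131.8 to -122.1 and the 9 libraries with LPS at 70.9 to 93.56. In media the most abundant genes were Psap (2.61% of counts) and Ctsb (2.56%), which encode a sphingolipid activator precursor and cathepsin B, and with LPS the most abundant was the ferritin heavy chain gene Fth1 (2.11%).

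CS against media shows what the CS stimulus did on its own. Interferon-stimulated genes rose as a group: 36 of 36 tested members were higher, 23 of them at least 2-fold, with a median of 1.32. Cxcl10, a chemokine that attracts T cells (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889 on GRCm38), rose from 3 ± 0.569 to 17.3 ± 1.84 CPM (2.55 ± 0.09, adjusted p = 7e-14). Ifit1bl1, of the interferon-induced IFIT family (ENSMUSG00000079339.7, chromosome 19, 34592891 to 34601956), rose from 2.21 ± 0.272 to 14.5 ± 1.24 CPM (2.7 ± 0.089, adjusted p = 2.6e-14). Genes of cholesterol synthesis fell, 22 of 23 with a median of -0.62, among them the squalene-forming enzyme gene Fdft1, from 21.1 ± 0.279 to 12.1 ± 0.0753 CPM (-0.80 ± 0.039).

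The interferon-stimulated rise included the antiviral genes Mx1 (2.23 ± 0.057) and Rsad2 (1.67 ± 0.037) and the guanylate-binding protein genes Gbp5 (2.18 ± 0.054) and Gbp2 (1.73 ± 0.045). Its levels stayed far below those with LPS: Rsad2 reached 102 ± 4.07 CPM with CS and 17000 ± 336 CPM with LPS. Antigen presentation genes rose in 17 of 19 cases, with a median of 0.62; the peptide transporter Tap1 (0.62 ± 0.032) and the class II gene H2-Ab1 (0.90 ± 0.057) were among them. Of the NF-kB feedback regulators 16 of 20 rose and 1 fell, with Birc3 at 0.79 ± 0.033 and Nfkbie at 0.87 ± 0.053. Macrophage identity genes rose in 14 of 20 cases and fell in 2, with the complement gene C1qa at 0.95 ± 0.044 and the integrin gene Itgam at 0.62 ± 0.036. Camera, a test of a list against all other genes, gave adjusted p = 1.3e-165, 5.7e-15, 1.7e-11 and 7.5e-14 for these 4 lists, all upwards, and 5.5e-40 downwards for cholesterol synthesis. All 5 calls were kept when the correlation between genes was estimated for each list (adjusted p = 0.00031, 0.015, 0.047, 0.0046 and 0.00012 with an estimated correlation). Counts adjusted over the list alone were the same except for the NF-kB feedback regulators, with 18 rises.

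Cytokine and chemokine genes moved less uniformly with CS, 11 of 30 rising and 3 falling (13 and 3 adjusted over the list alone). Tnf rose by 0.52 ± 0.062 to 9.57 ± 0.42 CPM and Il1b by 1.22 ± 0.15 to 1.55 ± 0.203 CPM, while Ccl3 fell by 0.93 ± 0.05. The median of 0.44 became 0.38 with Cxcl11 and Il6 set at what their counts allow; camera gave adjusted p = 0.0028, and adjusted p = 0.097 with an estimated correlation. Il6 had 1 count over the media libraries and 4 over the CS libraries, a ratio of 4 with a counting interval of 0.396 to 197, and Ifnb1 had 1 count in each group, so no change was detectable at this depth. Intervals and floors here cover counting error only. Nos2, the inducible nitric oxide synthase gene, was at 0.254 ± 0.0509 CPM in media and 0.365 ± 0.091 CPM with CS (adjusted p = 0.10). Acod1, whose product makes itaconate, rose by 1.17 ± 0.065. Of the 14 inducible effector enzyme genes 6 rose and none fell (6 and 0 adjusted over the list alone), with camera adjusted p = 0.01, and adjusted p = 0.15 with an estimated correlation. Of the alternative activation markers 6 of 11 rose (7 adjusted over the list alone, camera adjusted p = 0.0011), among them the lectin gene Clec10a at 0.97 ± 0.063.

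Among metabolic genes, 9 of the 16 fatty acid synthesis genes fell with CS (10 adjusted over the list alone, median -0.21, camera adjusted p = 7.5e-08), with fatty acid synthase, Fasn, at -0.79 ± 0.047 and the desaturase Fads2 at -0.82 ± 0.049. Fatty acid oxidation genes gave 7 rises and 4 falls of 20 (7 and 4 adjusted over the list alone) and no list call (camera adjusted p = 0.27), with the carnitine palmitoyltransferase gene Cpt1a at 0.81 ± 0.032. Lysosome and autophagy genes fell in 27 of 48 cases and rose in 6 (27 and 6 adjusted over the list alone, median -0.13, camera adjusted p = 9.5e-08). Ribosome biogenesis genes fell in 28 of 36 (31 adjusted over the list alone, median -0.26, camera adjusted p = 1.3e-07), with the nucleolar genes Gnl3 at -0.58 ± 0.06 and Ddx21 at -0.44 ± 0.038. FOXO-associated genes rose in 12 of 20 cases (13 adjusted over the list alone, camera adjusted p = 0.00035), with the sestrin gene Sesn3 at 0.85 ± 0.047. The p53-associated genes rose in 11 of 17 (11 adjusted over the list alone, camera adjusted p = 2.4e-05), with the cell cycle inhibitor gene Cdkn1a at 0.95 ± 0.036. The mitochondrial dynamics and mitophagy list fell in 16 of 32 cases (18 adjusted over the list alone, median -0.13, camera adjusted p = 0.0054, 0.049 with an estimated correlation). These list calls were kept with an estimated correlation, fatty acid oxidation having none.

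Several further lists were called with CS by camera but not with an estimated correlation. Glycolysis genes fell in 15 of 22 cases and the nuclear-encoded respiratory chain in 29 of 63 (16 and 34 adjusted over the list alone; adjusted p = 0.14 and 0.17 with an estimated correlation). The neuronal-type enolase gene Eno2 was at -0.80 ± 0.046. Ribosomal protein genes fell in 24 of 76 cases and endoplasmic reticulum chaperones in 13 of 22, with 0 and 2 rises (the same counts adjusted over the list alone). Their calls had camera adjusted p = 0.00052 and 0.0018, and adjusted p = 0.48 and 0.096 with an estimated correlation. Liver X receptor targets rose in 8 of 11 cases, with the cholesterol exporter Abca1 at 0.79 ± 0.029 (8 adjusted over the list alone, and adjusted p = 0.066 with an estimated correlation). Oxidative stress genes rose in 14 of 21, with Osgin1 at 0.97 ± 0.06 (15 adjusted over the list alone, and adjusted p = 0.18 with an estimated correlation). Cell death genes rose in 20 of 31 cases and fell in 5 (the same counts adjusted over the list alone; adjusted p = 0.066 with an estimated correlation). The inflammasome sensor Nlrp3 was at 0.70 ± 0.057 and the noncanonical inflammasome caspase Casp4 at 0.66 ± 0.058. Immediate early genes rose in 9 of 21 cases, with Fos at 1.09 ± 0.063 (9 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). The amino acid stress response, which changed strongly in later comparisons, gave 7 rises and 12 falls of 36 with CS (8 and 14 adjusted over the list alone, camera adjusted p = 0.46), with a median of -0.08 and a mean of 0.04. Ddit3, the stress transcription factor CHOP, was at -0.11 ± 0.038 (adjusted p = 0.031), a call lost in some alternative fits, and Trib3 (0.31 ± 0.18) and Gdf15 (-0.21 ± 0.091) did not pass the test. Ninj1, which encodes a protein of plasma membrane rupture, rose by 0.29 ± 0.038, and Gsdmd, which encodes the pore-forming gasdermin D, by 0.17 ± 0.043.

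Markers of other cell types were mixed with CS. Mmp8, from the neutrophil list, rose by 1.27 ± 0.061 and the immunoglobulin gene Ighm, from the lymphocyte list, by 1.03 ± 0.046; Kit, from the erythroid and mast cell list, fell by 1.74 ± 0.10. Those 3 lists had 4, 4 and 1 tested members, too few for a list test. Stromal markers gave 1 rise and 2 falls of 13 and dendritic cell markers 2 rises of 7 (camera adjusted p = 0.55 and 0.59; 1 rise, 2 falls and no call adjusted over the list alone). Across all genes, 5109 of 15496 passed adjusted p under 0.05 in edgeR, 2629 higher and 2480 lower, and 381 of them differed by at least 2-fold, 322 higher and 59 lower. The largest falls past the rule for named genes were in the deiodinase gene Dio2 (-1.51 ± 0.061) and the integrin gene Itgb3 (-1.48 ± 0.042).

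**Figure D1:**
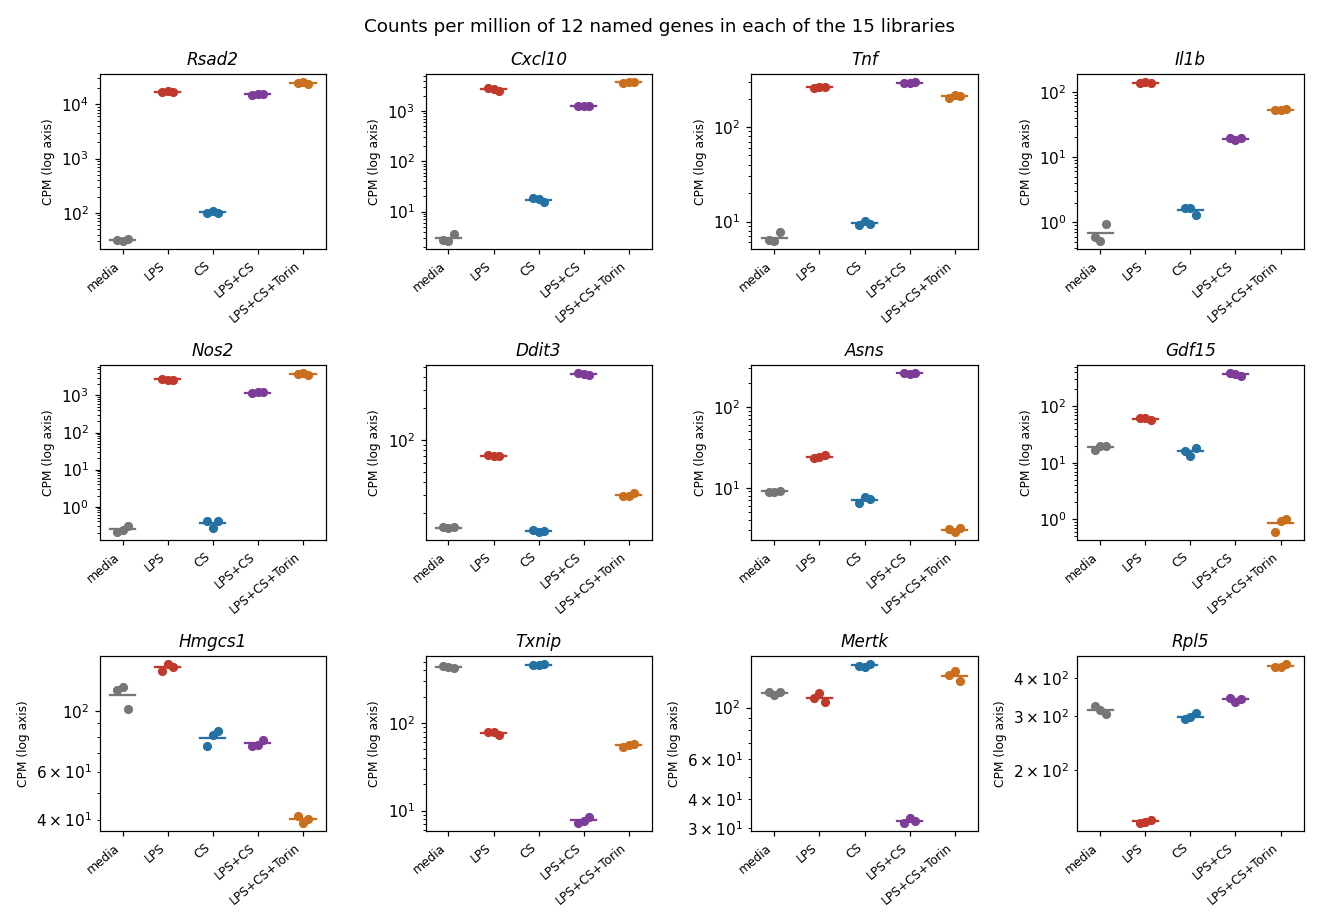
Levels of 12 named genes in each library (points; TMM-scaled CPM, logarithmic axis) by group, with a line at each group mean of 3 libraries. Rsad2, Cxcl10, Tnf, Il1b and Nos2 were high only in the groups with LPS, and Ddit3, Asns and Gdf15 were highest with LPS+CS and lower with LPS+CS+Torin, where Gdf15 was at 0.854 CPM against 365 with LPS+CS.

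LPS against media shows the response to LPS alone. Interferon-stimulated genes all rose, 36 of 36 at least 2-fold with a median of 7.52, and Rsad2 went from 32.2 ± 1.4 to 17000 ± 336 CPM (9.04 ± 0.048, adjusted p = 2.6e-28). Cytokine and chemokine genes rose in 29 of 30 cases: Ccl5, a T cell chemoattractant, from 1.96 ± 0.24 to 3970 ± 131 CPM and Tnf from 6.76 ± 0.776 to 263 ± 5.17 CPM (5.30 ± 0.056). Nos2 (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254) rose from 0.254 ± 0.0509 to 2690 ± 96.3 CPM (13.41 ± 0.09, adjusted p = 4.8e-27). Txnip, an inhibitor of thioredoxin and of glucose uptake (ENSMUSG00000038393.14, chromosome 3, 96557957 to 96561883), fell from 436 ± 10.7 to 76.7 ± 3.21 CPM (-2.51 ± 0.04). Ribosome biogenesis genes fell in 33 of 36 cases, with a median of -1.50 (camera adjusted p = 1.2e-07, and adjusted p = 0.070 with an estimated correlation).

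Genes without counts in media gave only lower bounds. Lcn2, an iron-scavenging lipocalin, was at least 7940-fold higher with LPS, and the chemokine Cxcl11 at least 7390-fold, against a floor of 3 counts over the media libraries. Il6 had 1 count in media and a ratio of 1760 (counting interval 316 to 69600), and Ifnb1, which encodes interferon beta, a ratio of 1340 (240 to 53000). Il1b rose by 7.72 ± 0.088 to 138 ± 2.83 CPM and Il10, an anti-inflammatory cytokine gene, by 6.38 ± 0.11 to 30.8 ± 2.37 CPM. Il1rn, the interleukin-1 receptor antagonist gene, reached 7530 ± 188 CPM (8.18 ± 0.058). The median of the cytokine list was 4.92, or 4.71 with the genes near the floor at their bounds.

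Other activation lists moved with LPS in the same direction. All 14 inducible effector enzyme genes rose (median 6.18), with Acod1 at 9.76 ± 0.073, the prostaglandin E synthase gene Ptges at 8.42 ± 0.06 and the mitochondrial superoxide dismutase gene Sod2 at 4.65 ± 0.032. All 20 NF-kB feedback regulators rose (median 2.49), with Socs3 at 7.75 ± 0.055 and Tnfaip3 at 4.27 ± 0.035. Antigen presentation genes rose in 18 of 19 cases (median 2.24), with Tap1 at 4.62 ± 0.034 and the costimulatory receptor Cd40 at 8.08 ± 0.06. Cell death genes rose in 25 of 31 cases and fell in 4 (median 1.51), with Casp4 at 5.19 ± 0.055 and the necroptosis effector Mlkl at 4.67 ± 0.058. Camera gave adjusted p = 1.6e-152 for the interferon-stimulated list, 3.8e-31 for cytokines, 1.4e-30 for effector enzymes, 1.9e-22 for NF-kB feedback, 3.4e-16 for antigen presentation and 9.1e-10 for cell death. These calls were kept with an estimated correlation, where the adjusted p ranged from 0.00096 for the interferon-stimulated list to 0.020 for NF-kB feedback and antigen presentation. The counts of these lists adjusted over the list alone were the same. With library totals only, rises and falls were 17 and 3 for NF-kB feedback and 13 and 1 for effector enzymes. They were 15 and 1 for antigen presentation, 20 and 9 for cell death, 27 and 0 for cytokines and 36 and 0 for the interferon-stimulated list. All these medians stayed above 0, from 0.73 for cell death to 6.74 for the interferon-stimulated list.

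The amino acid stress response rose with LPS in 26 of 36 cases and fell in 7 (26 and 7 adjusted over the list alone, median 1.59, camera adjusted p = 0.00013, and adjusted p = 0.19 with an estimated correlation). Ddit3 rose from 14.7 ± 0.215 to 70.7 ± 1.09 CPM (2.27 ± 0.036), Trib3 by 3.43 ± 0.13 and the folate cycle gene Mthfd2 by 4.25 ± 0.064. Ribosome biogenesis genes (33 falls adjusted over the list alone) included Utp20 at -3.40 ± 0.063 and Mybbp1a at -2.27 ± 0.047. Ribosomal protein genes fell in 66 of 76 cases and rose in 4 (the same adjusted over the list alone, median -0.40, camera adjusted p = 0.00028, and adjusted p = 0.43 with an estimated correlation). With library totals only the median of the stress response was 0.81, with 22 rises and 11 falls, and that of the ribosomal proteins -1.17, with 76 falls. Rpl5 fell by 1.21 ± 0.029; it shares sequence with the pseudogene Gm15500, so its level is uncertain, and with the reads of its copies added the change was -1.21. FOXO-associated genes fell in 15 of 20 cases, with the sestrin gene Sesn1 at -4.84 ± 0.07 (15 adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.070 with an estimated correlation). Fatty acid oxidation genes fell in 15 of 20, with Hadh at -2.60 ± 0.062 and Acadm at -2.19 ± 0.055 (15 adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.054 with an estimated correlation). Macrophage identity genes rose in 13 of 20 cases and fell in 5 (median 0.76, adjusted p = 0.069 with an estimated correlation), but the median was -0.02 with library totals only; the Fc receptor gene Fcgr1 was at 5.27 ± 0.03. Immediate early genes rose in 15 of 21 cases (adjusted p = 0.39 with an estimated correlation), with the phosphatase gene Dusp1 at 4.91 ± 0.047.

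Some groups had no common direction with LPS, or one that depended on the scaling. Glycolysis genes rose in 17 of 22 cases (17 adjusted over the list alone, median 0.50, camera adjusted p = 0.0078, and adjusted p = 0.40 with an estimated correlation), but the median was -0.28 with library totals only. Pfkfb3 was at 5.08 ± 0.053 and hexokinase 3, Hk3, at 2.91 ± 0.035. Endoplasmic reticulum chaperones (0.38), heat shock genes (0.63), cholesterol synthesis (0.33), liver X receptor targets (0.36) and stromal markers (0.33) had medians above 0 that were below 0 with library totals only. None was called by camera (adjusted p = 0.44, 0.16, 0.61, 0.86 and 0.88). Within cholesterol synthesis Dhcr7 fell by 2.25 ± 0.082; the stromal proteoglycan gene Dcn rose by 2.04 ± 0.11. Medians of the lysosome and autophagy (0.18), oxidative stress (0.13), hypoxia (0.18), respiratory chain (0.01) and dendritic cell (0.25) lists turned negative with upper quartile factors as well as with library totals. The median of mitochondrial dynamics and mitophagy (-0.02) turned positive with RLE factors and DESeq2 size factors. Camera called none of these lists (adjusted p = 0.39, 0.27, 0.86, 0.87, 0.92 and 0.47). Camera pointed down for the respiratory chain, dendritic cell and hypoxia lists, the last with a mean of -0.03. The mTOR pathway components gave 12 rises and 18 falls of 34 (camera adjusted p = 0.35). The mTOR inhibitor gene Deptor was at -5.46 ± 0.08, Rictor at 1.54 ± 0.037, Rptor at -0.49 ± 0.041 and Mtor at 0.01 ± 0.036 (adjusted p = 0.77). Cell cycle genes gave 9 rises and 20 falls of 34 (camera adjusted p = 0.75), with the spindle gene Tpx2 at 5.07 ± 0.062. The p53-associated genes gave 4 rises and 11 falls of 17 (median -0.63, camera pointing up with adjusted p = 0.97). Alternative activation markers gave 5 rises and 6 falls of 11 (median -0.28, mean 0.49, camera adjusted p = 0.94), with Il4ra at 3.41 ± 0.031 and the transferrin receptor gene Tfrc at -3.56 ± 0.071. The 16 fatty acid synthesis genes split into 5 rises and 10 falls (camera adjusted p = 0.56), with the acyl-CoA synthetase gene Acsl1 at 5.14 ± 0.038 and Fasn at -1.18 ± 0.049.

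Transcripts of the mitochondrial genome made up 2.18 ± 0.0753% of counts in media and 1.02 ± 0.0112% with LPS. These shares are of unscaled library totals and leave out reads assigned to near-identical nuclear copies. They are therefore not on the scale of the TMM-scaled changes that follow. Of 13 mitochondrially encoded mRNAs 12 fell and mt-Co1 rose (12 and 1 adjusted over the list alone, median -1.18, camera adjusted p = 0.062), but with upper quartile factors or library totals only all 13 fell. The level of mt-Nd1 fell from 1280 ± 98 to 414 ± 5.54 CPM (-1.63 ± 0.051). Several of these genes share long stretches with nuclear copies in the annotation, which makes their levels uncertain; with the reads of the copies added the median was -0.78, again with 12 falls and 1 rise. Ninj1 (ENSMUSG00000037966.15, chromosome 13, 49187485 to 49196244) rose with LPS from 165 ± 7.87 to 468 ± 7.26 CPM (1.51 ± 0.039, adjusted p = 5.1e-18), and Gsdmd by 2.79 ± 0.043. Kit fell by 1.70 ± 0.11 and Ighm by 3.18 ± 0.065. In all, 12738 genes passed the test, 6169 higher and 6569 lower, of which 3177 and 3232 by at least 2-fold. With upper quartile factors the split was 4936 higher and 8090 lower, and with library totals only it was 3170 and 10640. The median of all genes moved by -0.26 and -0.77. TMM factors were 1.388 to 1.393 in media and 0.8048 to 0.8179 with LPS.

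LPS+CS against LPS shows what CS added in cells that also received LPS. The amino acid stress response, a programme driven by the transcription factor ATF4, rose in 34 of 36 cases and fell in none, with a median of 1.71. Trib3, an ATF4 target and pseudokinase (ENSMUSG00000032715.9, chromosome 2, 152337422 to 152344032), rose from 14.4 ± 0.696 to 202 ± 4.53 CPM (3.81 ± 0.088, adjusted p = 8.8e-18). Asns, the asparagine synthetase gene (ENSMUSG00000029752.12, chromosome 6, 7675169 to 7693254), rose from 24.3 ± 1.23 to 260 ± 3.57 CPM. Ddit3 (ENSMUSG00000025408.15, chromosome 10, 127290774 to 127296288) rose from 70.7 ± 1.09 to 424 ± 10.4 CPM. Genes of cholesterol synthesis fell in 21 of 23 cases and rose in 2, with a median of -1.20. Il1b fell from 138 ± 2.83 to 19.1 ± 0.763 CPM (-2.86 ± 0.059, adjusted p = 1.6e-18), while Tnf was at 263 ± 5.17 and 294 ± 4.65 CPM (0.16 ± 0.043, adjusted p = 0.0027).

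The stress response also held the cationic amino acid transporter Slc7a1 (3.30 ± 0.052), Atf5 (2.77 ± 0.047) and the stress hormone gene Gdf15 (2.61 ± 0.082), and Txnip fell further, to 7.81 ± 0.664 CPM (-3.29 ± 0.05). Cholesterol synthesis included Idi1 (-1.64 ± 0.043) and Hmgcs1 (-0.92 ± 0.058). Fatty acid synthesis genes fell in 13 of 16 cases (median -0.71), with the stearoyl-CoA desaturase gene Scd2 from 365 ± 23.6 to 43.4 ± 3.31 CPM (-3.07 ± 0.06). Macrophage identity genes fell in 14 of 20 cases and rose in 3 (median -0.39), with the transcription factor gene Maf at -2.03 ± 0.033 and Mertk, a receptor for apoptotic cells, at -1.77 ± 0.042. Camera gave adjusted p = 3.1e-63 upwards for the stress response and 1.3e-16, 5.2e-06 and 1.9e-07 downwards for cholesterol synthesis, fatty acid synthesis and macrophage identity. These 4 calls were kept with an estimated correlation (adjusted p = 0.00017, 0.0040, 0.0096 and 0.020 with an estimated correlation). Adjusted over the list alone the counts were the same except for macrophage identity, with 4 rises.

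Ribosomal protein genes rose in 75 of 76 cases (75 adjusted over the list alone, median 0.63, camera adjusted p = 9.1e-18, and adjusted p = 0.067 with an estimated correlation), with Rpl4 at 1.10 ± 0.031. Ribosome biogenesis genes rose in 28 of 36 (28 adjusted over the list alone, median 0.56, adjusted p = 0.069 with an estimated correlation), with Gnl3 at 2.40 ± 0.072. Lysosome and autophagy genes rose in 32 of 48 cases and fell in 7 (32 and 8 adjusted over the list alone, camera adjusted p = 5.8e-05, and adjusted p = 0.053 with an estimated correlation). The autophagy receptor gene Sqstm1 went from 1510 ± 27.3 to 6060 ± 98.2 CPM (2.01 ± 0.038). Endoplasmic reticulum chaperones rose in 14 of 22 cases and fell in 7 (14 and 7 adjusted over the list alone, adjusted p = 0.10 with an estimated correlation), with Herpud1 at 2.49 ± 0.056 and the stress sensor Ern1 at 1.95 ± 0.034. Cell cycle genes fell in 22 of 34 cases (22 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation), with the ribonucleotide reductase gene Rrm1 at -1.59 ± 0.06. Glycolysis genes fell in 15 of 22 (15 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation), with Tpi1 at -1.47 ± 0.035. Fatty acid oxidation genes fell in 18 of 20 cases (18 adjusted over the list alone, adjusted p = 0.074 with an estimated correlation). The p53-associated genes rose in 9 of 17 and fell in 4 (9 and 4 adjusted over the list alone, adjusted p = 0.050 with an estimated correlation), with Mdm2 at 1.12 ± 0.034. The hypoxia list was called upwards by camera (adjusted p = 6.2e-05, 0.016 with an estimated correlation) with a mean of 0.22 but a median of -0.12, from 8 rises and 9 falls of 18 (8 and 9 adjusted over the list alone). Ndrg1 (3.04 ± 0.044) and Bhlhe40 (2.91 ± 0.042) rose most among its named members.

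Inflammatory genes went both ways when CS was added to LPS. Cytokines and chemokines gave 11 rises and 17 falls of 30 (11 and 18 adjusted over the list alone, camera adjusted p = 0.026 downwards, and adjusted p = 0.13 with an estimated correlation). Values were mixed, with Ccl7 at -1.98 ± 0.043, Il10 at -1.24 ± 0.068, Ifnb1 at -0.61 ± 0.10, Il6 at 0.66 ± 0.10, Cxcl2 at 1.70 ± 0.045 and the macrophage growth factor gene Csf1 at 1.58 ± 0.036. NF-kB feedback regulators gave 13 rises and 5 falls of 20 (adjusted p = 0.27 with an estimated correlation), with Nfkb2 at 1.35 ± 0.034 and Tnip3 at -1.85 ± 0.046. Interferon-stimulated genes gave 17 rises and 15 falls of 36 (17 and 15 adjusted over the list alone, camera adjusted p = 0.66), with a median of 0.08 that became -0.03 with upper quartile factors or library totals only. Effector enzymes gave 5 rises and 6 falls of 14 (camera adjusted p = 0.95), with Nos2 from 2690 ± 96.3 to 1190 ± 36 CPM (-1.18 ± 0.044) and the cyclooxygenase gene Ptgs2 at 1.89 ± 0.045. Cell death genes gave 13 rises and 11 falls of 31 (camera adjusted p = 0.97) with a mean of -0.04 and a median of 0.04 that was negative with upper quartile factors or library totals only. The inflammasome adaptor gene Pycard fell by 2.06 ± 0.052. Bcl2a1b rose by 1.28 ± 0.044, or 1.39 with the reads of its near-identical copies Bcl2a1d and Gm29094 added, and its own level is uncertain. Ninj1 rose from 468 ± 7.26 to 697 ± 19 CPM (0.57 ± 0.038), and Gsdmd was at -0.05 ± 0.039 (adjusted p = 0.28). The mTOR pathway components gave 14 rises and 13 falls of 34, with a median of 0.02 that was negative with upper quartile factors or library totals only. The arginine sensor gene homologue Castor2 fell by 3.18 ± 0.05, and Sgk1 (1.93 ± 0.033) and Rragd (2.01 ± 0.059) rose.

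Stromal markers fell beside these changes, 11 of 13 with 1 rise (11 and 1 adjusted over the list alone, median -1.46, camera adjusted p = 3.1e-06, and adjusted p = 0.054 with an estimated correlation). The collagen genes Col1a1 and Col1a2 went from 79.6 ± 6.09 to 18.2 ± 1 CPM and from 71.9 ± 3 to 19.4 ± 1.19 CPM, and Sparc fell by 2.23 ± 0.074. Dendritic cell markers gave 1 rise and 4 falls of 7 (camera adjusted p = 0.59), and Kit rose by 1.26 ± 0.11. Heat shock genes gave 4 rises and 8 falls of 14 (median -0.24, camera pointing up with adjusted p = 0.88), with the mitochondrial chaperone gene Hspa9 at 2.79 ± 0.042. Mitochondrially encoded mRNAs gave 3 rises and 3 falls of 13 (camera adjusted p = 0.98), with a median of 0.11 that came to 0 or less with upper quartile factors or library totals only. The largest changes past the rule for named genes included Aqp9, a channel for glycerol and water, at 3.82 ± 0.062 and Inhba, which encodes an activin subunit, at 3.61 ± 0.051. In all 10448 genes passed the test, 5129 higher and 5319 lower, and 1030 and 1672 of them by at least 2-fold. With upper quartile factors and with library totals only the split was 4229 and 6297, and 4205 and 6305, the median of all genes moving by -0.11 in both.

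The interaction of LPS and CS, the change by CS with LPS minus the change by CS without it, tests where the joint stimulus departed from the sum of the single effects on the log2 scale. It was positive for the amino acid stress response, 32 of 36 members with 1 negative and a median of 1.93, including Asns (3.75 ± 0.072, adjusted p = 2.3e-18), Trib3 (3.50 ± 0.21), Gdf15 (2.83 ± 0.12) and Ddit3 (2.7 ± 0.05). It was negative for the interferon-stimulated genes, 35 of 36 with a median of -1.04, including Mx1 (-2.7 ± 0.068) and Ifit1 (-2.37 ± 0.064). These rose with CS alone and had no common direction with CS on top of LPS. LPS alone raised this list by a median of 7.52 and CS alone by 1.32, so an equal gain in CPM would hardly show beside LPS. Their negative values on the log2 scale thus need not mean that CS acted differently beside LPS. The interaction was also negative for macrophage identity genes, 16 of 20 with 1 positive and a median of -0.92. These included Maf (-2.33 ± 0.045) and Mertk (-2.16 ± 0.056). The highest value past the rule for named genes was 4.15 ± 0.056 for Arfgef3, which went from 117 ± 2.25 to 48.3 ± 0.51 CPM with CS alone and from 30.8 ± 1.18 to 225 ± 5.54 CPM with CS on top of LPS. The lowest past the rule was -5.10 ± 0.67 for Lrrc4, which had only 4 counts over the media libraries.

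Camera gave adjusted p = 1.4e-41 for the stress response, 6.1e-25 for the interferon-stimulated list and 1e-13 for macrophage identity, and these calls were kept (adjusted p = 0.00013, 0.039 and 0.0048 with an estimated correlation). Lysosome and autophagy genes had positive interactions in 36 of 48 cases and negative ones in 8 (camera adjusted p = 1.5e-08, 0.012 with an estimated correlation), with Sqstm1 at 1.96 ± 0.052 and the proton pump gene Atp6v1c1 at 1.61 ± 0.048. Ribosomal protein genes were positive in 76 of 76 cases (median 0.73, camera adjusted p = 2.2e-19, and adjusted p = 0.058 with an estimated correlation), with Rpl4 at 1.21 ± 0.043. Ribosome biogenesis genes were positive in 30 of 36 (camera adjusted p = 8.3e-08, 0.020 with an estimated correlation), with Gnl3 at 2.99 ± 0.094. Endoplasmic reticulum chaperones were positive in 16 of 22 cases (camera adjusted p = 5.3e-05, 0.049 with an estimated correlation), with Herpud1 at 2.29 ± 0.076. The hypoxia list was called upwards (camera adjusted p = 8.9e-05, 0.020 with an estimated correlation) with a mean of 0.29 and a median of -0.10, and Bhlhe40 was at 3.76 ± 0.058. Adjusted over the list alone, these 8 lists, in the order given, had 32, 0, 1, 36, 76, 30, 17 and 8 positive and 1, 35, 16, 8, 0, 2, 4 and 9 negative members.

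Several downward interaction calls were lost with an estimated correlation. Cytokines and chemokines were negative in 18 of 30 cases and alternative activation markers in 6 of 11 (adjusted p = 0.20 and 0.10 with an estimated correlation). Cholesterol synthesis was negative in 15 of 23 cases, fatty acid synthesis in 11 of 16 and fatty acid oxidation in 16 of 20 (adjusted p = 0.15, 0.092 and 0.054 with an estimated correlation). Cell cycle genes were negative in 21 of 34 cases and stromal markers in 11 of 13 (adjusted p = 0.33 and 0.067 with an estimated correlation). The mTOR pathway components, 16 of 34 positive with a median of 0.06 that turned negative with upper quartile factors or library totals only, were called upwards by camera (adjusted p = 0.040, and adjusted p = 0.15 with an estimated correlation). Named members included Cxcl10 (-3.63 ± 0.11), Ccl12 (-4.45 ± 0.31), Il1b (-4.08 ± 0.16) and Il10 (-2.12 ± 0.22). Others were Il4ra (-2.43 ± 0.04), Scd2 (-2.96 ± 0.079), Cpt1a (-1.11 ± 0.046), Castor2 (-3.23 ± 0.063) and Sparc (-2.28 ± 0.096). Effector enzyme genes had 4 positive and 7 negative interactions of 14 and no list call (camera adjusted p = 0.57), with Nos2 at -1.74 ± 0.26 and Acod1 at -1.47 ± 0.081. Txnip was at -3.38 ± 0.063, Hmgcs1 at -0.40 ± 0.081 and Tnf at -0.36 ± 0.075. Rictor was at 0.36 ± 0.052, Rptor at 0.21 ± 0.058, Ninj1 at 0.28 ± 0.054 and Gsdmd at -0.22 ± 0.058, while Mtor was at -0.10 ± 0.05 (adjusted p = 0.099). In all 9592 genes passed the edgeR test of the interaction, 4631 positive and 4961 negative, and 1096 and 2022 of them by at least 1 on the log2 scale. With upper quartile factors the split was 3816 and 5856, and with library totals only 3682 and 5984, the median of all genes moving by -0.11 and -0.13.

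**Figure D2:**
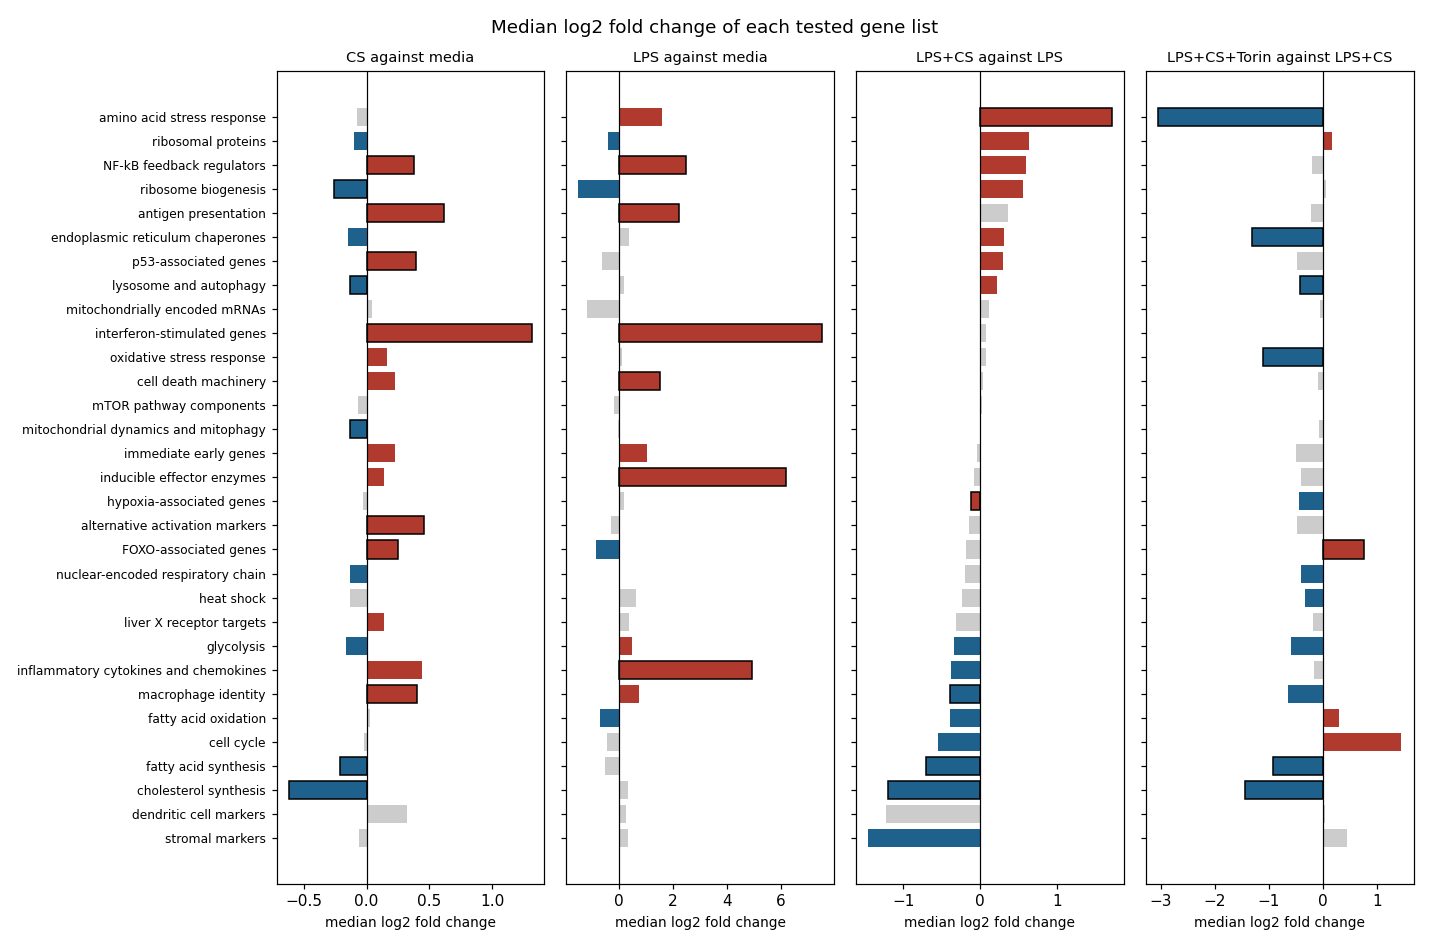
Median log2 fold change of each gene list (bars from 0) in 4 comparisons, 1 panel each; red bars were called up and blue bars called down by camera, grey bars were not called, and a black edge marks calls kept with an estimated correlation. The amino acid stress bar is at 1.71 for LPS+CS against LPS and at -3.06 for LPS+CS+Torin against LPS+CS; bars near 0 change sign with the scaling, such as interferon-stimulated genes for LPS+CS against LPS (0.08, or -0.03 with library totals only).

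LPS+CS+Torin against LPS+CS shows what the mTOR inhibitor changed in doubly stimulated cells. The amino acid stress response fell in 35 of 36 cases and rose in 1, with a median of -3.06. Gdf15 (ENSMUSG00000038508.7, chromosome 8, 70629393 to 70632456) went from 365 ± 21.9 to 0.854 ± 0.22 CPM (-8.74 ± 0.13, adjusted p = 1.9e-20). Trib3 went from 202 ± 4.53 to 1.14 ± 0.126 CPM (-7.46 ± 0.12) and Asns from 260 ± 3.57 to 3.02 ± 0.17 CPM (-6.43 ± 0.06). Endoplasmic reticulum chaperone genes fell in 21 of 22 cases (median -1.31) and cholesterol synthesis genes in 22 of 23 (median -1.44). FOXO-associated genes rose in 17 of 20 cases and fell in 2 (median 0.76), with Cited2 from 50.5 ± 2.61 to 242 ± 11.6 CPM. Nos2 rose from 1190 ± 36 to 3750 ± 235 CPM (1.66 ± 0.045) and Il1b from 19.1 ± 0.763 to 53.6 ± 1.09 CPM (1.49 ± 0.059).

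Further members of the stress response were the glutathione-degrading enzyme gene Chac1 (-8.59 ± 0.14), Sesn2 (-5.42 ± 0.062), the alanyl-tRNA synthetase gene Aars (-3.54 ± 0.037) and Ddit3 (-3.82 ± 0.035, to 30 ± 0.984 CPM). Herpud1 fell by 6.11 ± 0.08, and the chaperone genes Calr and Hyou1 by 1.87 ± 0.034 and 2.06 ± 0.044. In cholesterol synthesis, Idi1 was at -3.12 ± 0.064 and Insig1 at -1.95 ± 0.046. Fatty acid synthesis genes fell in 13 of 16 cases (median -0.93), with Scd2 at -2.25 ± 0.073. Lysosome and autophagy genes fell in 40 of 48 cases and rose in 4 (median -0.42); the cathepsin D gene Ctsd went from 9720 ± 89.7 to 1680 ± 28.7 CPM (-2.53 ± 0.026), and Hexa was at -1.74 ± 0.028. Oxidative stress genes fell in 19 of 21 cases (median -1.12), with Srxn1 at -2.40 ± 0.039 and the thioredoxin reductase gene Txnrd1 at -1.94 ± 0.034. Camera gave adjusted p = 4e-106 for the stress response, 1.8e-24 for chaperones, 3.9e-16 for cholesterol synthesis, 8.4e-05 for fatty acid synthesis, 6.1e-12 for lysosome and autophagy, 3.4e-16 for oxidative stress and 1.9e-07 for FOXO. All 7 calls were kept with an estimated correlation, with an adjusted p from 2.7e-05 for the stress response to 0.020 for fatty acid synthesis, and all counts adjusted over the list alone were the same.

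Fatty acid oxidation and cell cycle genes were higher with Torin, in 12 of 20 cases with 6 falls and in 23 of 34 with 7 falls (the same counts adjusted over the list alone; camera adjusted p = 0.036 and 6.8e-05; adjusted p = 0.079 and 0.077 with an estimated correlation). Cpt1a went from 79.8 ± 0.33 to 425 ± 4.81 CPM (2.41 ± 0.034), and the replication helicase gene Mcm6 and topoisomerase gene Top2a were at 1.69 ± 0.06 and 1.94 ± 0.078. Ribosomal protein genes rose in 57 of 76 cases and fell in none (57 adjusted over the list alone, median 0.17, camera adjusted p = 0.0015, and adjusted p = 0.54 with an estimated correlation), with Rpl4 at 0.48 ± 0.03. Macrophage identity genes fell in 14 of 20 cases and rose in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 5.9e-05, and adjusted p = 0.053 with an estimated correlation). The lysozyme gene Lyz2 went from 8890 ± 265 to 1940 ± 98.5 CPM, while Mertk rose by 2.08 ± 0.042 to 138 ± 6.47 CPM. Glycolysis genes fell in 16 of 22 cases and the respiratory chain in 49 of 63 (16 and 49 adjusted over the list alone, and adjusted p = 0.17 and 0.33 with an estimated correlation). The pyruvate kinase gene Pkm was at -1.14 ± 0.03 and Uqcrq at -1.95 ± 0.088. Hypoxia and heat shock genes fell in 12 of 18 and 10 of 14 cases (12 and 10 adjusted over the list alone; adjusted p = 0.13 and 0.17 with an estimated correlation). Hif1a was at -1.17 ± 0.044, Ero1l at -2.87 ± 0.062 and Hspa9 at -3 ± 0.042.

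Inflammatory lists had no common direction with Torin. Interferon-stimulated genes gave 12 rises and 16 falls of 36 (camera adjusted p = 0.98), with a median of 0 that was above 0 with every other scaling. The majority turned to 20 rises and 7 falls with upper quartile factors, and to 20 and 9 with library totals only. Rsad2 was at 0.70 ± 0.033 and Isg15 at -1.13 ± 0.039. Cytokines and chemokines gave 9 rises and 15 falls of 30 (camera pointing up, adjusted p = 0.92), with a median of -0.16 that was 0.03 with upper quartile factors. Cxcl2 fell by 2.12 ± 0.046, Tnf by 0.48 ± 0.043, Tnfsf15 rose by 1.93 ± 0.056 and Ifnb1 by 0.81 ± 0.10. Il6 (0 ± 0.098, adjusted p = 1) and Il10 (0.02 ± 0.072, adjusted p = 0.83) did not pass the test. Effector enzymes gave 5 rises and 7 falls of 14 with a median of -0.41 and a mean of 0.02, and 6 rises and 6 falls with upper quartile factors (camera adjusted p = 0.98). Acod1 was at 0.05 ± 0.048 (adjusted p = 0.37). NF-kB feedback regulators gave 5 rises and 14 falls of 20 (camera adjusted p = 0.071) and antigen presentation genes 5 rises and 11 falls of 19 (adjusted p = 0.69), a majority that turned with upper quartile factors. Cell death genes gave 9 rises and 15 falls of 31 (camera adjusted p = 0.77), with a median of -0.10 that turned positive with upper quartile factors or library totals only. Ninj1 (-0.04 ± 0.038, adjusted p = 0.32) and Gsdmd (-0.02 ± 0.039, adjusted p = 0.69) did not pass the test. The mTOR pathway components gave 12 rises and 15 falls of 34, a majority that turned with upper quartile factors or library totals only (camera adjusted p = 0.64). Among them Rragd was at -2.90 ± 0.064, Eif4ebp1, a target of mTOR complex 1, at -2.33 ± 0.081, Mtor at 0.44 ± 0.036, Rictor at 0.54 ± 0.035 and Rptor at -0.50 ± 0.043. Txnip rose by 2.83 ± 0.051 to 55.7 ± 1.79 CPM.

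Stromal markers rose with Torin in 7 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.25), with Postn at 1.07 ± 0.094, and Kit fell by 1.81 ± 0.12 and Ighm by 1.49 ± 0.12. The largest rise past the rule for named genes was in Dennd3, an exchange factor for a Rab GTPase, from 0.802 ± 0.0224 to 12.5 ± 0.687 CPM (3.96 ± 0.11). In all 10885 genes passed the test, 5498 higher and 5387 lower, and 1782 and 1441 of them by at least 2-fold. With upper quartile factors the split was 7206 and 3977, and with library totals only 6786 and 4280, the median of all genes moving by 0.19 and 0.14.

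LPS+CS against CS and against media show the effect of LPS in the presence of CS and that of both stimuli together. Lcn2 rose from 0.0289 ± 0.0199 CPM with CS to 168 ± 6.57 CPM with LPS+CS, and was at least 11000-fold higher with LPS+CS than in media; Cxcl11 was at 80.8 ± 2.23 CPM with LPS+CS, at least 5290-fold over media. Abcd2, a peroxisomal fatty acid transporter gene, fell from 22.8 ± 1.05 CPM with CS and 16.3 ± 1 CPM in media to 0.0484 ± 0.0513 CPM (-8.70 ± 0.19 and -8.22 ± 0.21). Zfp395 fell from 46.6 ± 1.22 CPM with CS to 0.136 ± 0.0742 CPM, and Rasgrp3 from 47.5 ± 2.12 CPM in media to 0.0968 ± 0.0473 CPM. Against CS 13285 genes passed the test, 6478 higher and 6807 lower; the split was 4909 and 8548 with upper quartile factors and 3117 and 10889 with library totals only (medians moved by -0.37 and -0.91). Against media 13226 passed, 6455 higher and 6771 lower, with 4916 and 8523 for upper quartile factors and 3176 and 10782 for library totals only (medians moved by -0.37 and -0.88).

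Across the 15496 genes, changes were also compared between pairs of comparisons that share no library; genes are not independent replicates, so no p is given. The change with LPS ran parallel without and with CS (Pearson r = 0.86, Spearman rho = 0.82): of 11541 genes called in both, 10285 (89.1%) had the same sign. The change with CS differed without and with LPS (r = -0.10, rho = -0.16), with the same sign for 1514 of 4049 genes called in both (37.4%). For CS alone and Torin, r was 0.11 and rho 0.22, with the same sign for 2885 of 4194 genes (68.8%). For LPS alone and Torin r was -0.11 and rho -0.14, with the same sign for 3953 of 9374 (42.2%). Over genes with a mean CPM of at least 10 the 4 values of r, in the order given, were 0.90, -0.18, 0.18 and 0.01.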

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

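In the interaction of LPS and CS 9592 genes passed the edgeR test, so on the log2 scale their change with CS differed between cells with and without LPS. Named values were 4.15 for Arfgef3, 3.96 for Rps6ka2, 3.80 for Dio2, 3.76 for Bhlhe40, 3.50 for Trib3, 2.83 for Gdf15, 2.7 for Ddit3, 0.36 for Rictor, 0.28 for Ninj1 and 0.21 for Rptor. Negative values were -5.10 for Lrrc4, -4.45 for Ccl12, -4.33 for Ifit1bl1, -4.08 for Il1b, -3.38 for Txnip, -2.12 for Il10, -1.74 for Nos2, -1.47 for Acod1, -0.40 for Hmgcs1, -0.36 for Tnf and -0.22 for Gsdmd. The splits of samples were planned beforehand; the tests on LPS material, traces of LPS, mitochondrial copies and stromal cells were chosen only after the results were seen. For each comparison of 3 against 3 libraries the real grouping was the only 1 of 10 splits with as many called genes, and the highest other split had 0, or 1 for Torin; 10 splits are too few for a share under 0.05. For the interaction the real grouping was the only 1 of 100 splits with as many called genes. The 9 splits that kept LPS and LPS+CS apart but mixed media and CS gave 7554 to 8177 genes. Most of the real count could thus arise from the difference between LPS and LPS+CS alone.

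Interferon-stimulated genes rose with CS alone, which could come from LPS material in the CS libraries. Over 36 genes the rise would need a median share of 1.23% of the LPS level (interval 0.608 to 1.62). The 50 other genes near 0 in media and high with LPS allow 0.24% (0.127 to 0.381). This argues against a single share for the whole rise, though a share may account for part of it. The intervals treat genes as independent and leave out the spread between libraries. A correlation of 0.43 was estimated between the interferon-stimulated genes with CS, so the intervals are likely too narrow and a single share is not excluded. The bound used, that the intervals do not overlap, was set after the values were seen. It replaced an earlier bound, a fixed fraction of the interferon-stimulated share, under which the question stayed undecided. A weak response to traces of LPS in the CS samples remains possible: of 58 members of the other activation lists raised at least 2-fold by LPS, 29 rose with CS, 4 fell and 25 did not pass the test, with a median of 0.40. It stays open whether CS itself or a trace contaminant likely raised these genes.

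Mitochondrially encoded mRNAs fell unequally with LPS, from -2.71 to 0.11 over 13 changes with copies added, and no separate test was made of a lower yield of mitochondrial RNA acting beside other causes. For mt-Atp6, mt-Co2 and mt-Co3 the fall could come in part from reads assigned to nuclear copies, since their mean was -2.90 alone and -0.38 with the copies added. That drop rests largely on media replicate 3, where they were at 463, 186 and 172 CPM. From group mean CPM without it, a step added after the values were seen, the mean was -1.42 alone and -0.44 with copies. In CS replicate 1 mt-Atp6 was also high, at 423 CPM, with its copy Gm10925 at 1090, against 79.8 and 1700 in CS replicate 2. The copies, 100% identical over 678 to 783 nt, held 94.3, 97.8 and 97.4% of the summed counts. The fall of the genes alone thus depends on how reads were divided between gene and copy, which these counts cannot settle. The summed fall, -0.38 or -0.44, changed little without that media library. Most of the other 10 had no reads of a copy to add; with them mt-Nd3 went from -4.08 to -2.71 and mt-Nd4l from -1.05 to -1.30. What lowered those of the 10 that fell stays open, copies missed by the search included.

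Stromal markers fell with LPS+CS against LPS, which might reflect fewer stromal cells. Changes were unequal over the 13 markers, with a chi-square per degree of freedom of 141. Dcn rose by 1.17 while Col3a1 fell by 3.73, so a smaller share alone does not account for all 13. The chi-square cannot tell whether the share fell. Its standard errors cover only the spread between libraries, and 67.4% of all tested genes passed the test in this comparison. A high value was thus likely whatever the share of stromal cells. A smaller share together with regulation of single genes stays open.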

How the results depend on the processing

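Counts of called genes stayed within 1.5 times under every alternative except the limit of 1 on the absolute log2 fold change, which by construction left 381 genes for CS against media, 6409 for LPS against media, 2702 for LPS+CS against LPS, 7472 for LPS+CS against CS, 3118 for the interaction, 3223 for LPS+CS+Torin against LPS+CS and 7405 for LPS+CS against media. Leaving out 1 sample gave 4064 to 4890, 12449 to 12705, 9864 to 9998, 13088 to 13306, 9151 to 9587, 10357 to 10476 and 12975 to 13246 genes in that order. A block for the replicate number gave 4800, 12687, 10334, 13221, 9420, 10754 and 13145 genes. Residuals of samples with the same number correlated at -0.0995 to 0.0971 and of samples with different numbers at -0.148 to 0.172. No effect common to a replicate number was thus detectable, which cannot tell whether the numbers pair samples. The highest correlation, 0.172, was between media replicate 3 and CS replicate 1, the smallest libraries of their groups. Each ran at -0.148 to -0.0549 with the other libraries of the opposite group. Chi-square per degree of freedom was 16.2 and 12.3 for media pairs with replicate 3, and 2.61 for the other. For CS pairs it was 10.6 to 13.9. The cause was not tested. CS against media gave 4890 genes without that media library and 4883 without that CS library. Camera calls numbered 83, or 37 with an estimated correlation and 82 with the block. Fry gave 139 calls, but it tests whether a list changed at all rather than against the other genes, so its count is not comparable. Named genes were recomputed with RLE factors, DESeq2, limma-voom, the block and 1 sample left out, but not with upper quartile factors, library totals only or other filters, so small changes may turn with the scaling. Of 331 values 320 kept direction and side of the limit in the settings run, and of 316 past the test none reversed there; Ddit3 with CS lost its call with DESeq2, limma-voom and some samples left out.

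Reversals in these settings were of values not past the test, and the cause was not tested. Rptor with CS (0.00) was 0 with RLE factors and with DESeq2, and from -0.03 to 0.02 with 1 sample left out. Trib3 with CS (0.31) ranged from -0.05 without CS replicate 3 to 0.46 without media replicate 2. Mtor with LPS (0.01) ranged from 0 to 0.04, Il10 with Torin (0.02) from -0.02 to 0.04, and Il6 with Torin from -0.08 to 0.07, with 0 for the block and for limma-voom. Il6 and Ifnb1 in CS against media and in the interaction were left out here, since their counts do not determine a direction. Over genes with a mean of at least 10 CPM the correlation was -0.18 for CS against media with LPS+CS against LPS. It was 0.90 for LPS against media with LPS+CS against CS and 0.18 for CS against media with Torin. For LPS against media with Torin it was 0.01, a reversal. Over all tested genes the 4 correlations, in the same order, were -0.10, 0.86, 0.11 and -0.11. With 1 sample left out, those over all tested genes ranged from -0.11 to -0.07, 0.85 to 0.86, 0.10 to 0.14 and -0.11 to -0.10. Their jackknife SE were 0.038, 0.011, 0.044 and 0.017. Samples were not left out for the correlations over genes with at least 10 CPM. At this depth Il6 and Ifnb1 in media and CS, with 1 to 4 counts per group, could not be compared.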

Other observations

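Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, rose when CS was added to LPS in 14 of 20 cases and fell in 2 (median 0.90, camera adjusted p = 2.5e-15, 0.0016 with an estimated correlation), and with Torin 16 fell and 3 rose (median -1.79, adjusted p = 1.9e-26, 0.00056 with an estimated correlation). As 6 of them are also in the amino acid stress list, these values partly restate its change. Of the 14 others 8 rose and 2 fell with CS added to LPS (median 0.55), and 3 rose and 10 fell with Torin (median -0.72). With CS alone none of the 20 synthetase genes rose and 11 fell (median -0.15, adjusted p = 0.00083, 0.044 with an estimated correlation). Proteasome subunit genes rose with LPS in 32 of 32 cases (median 0.84, adjusted p = 1.1e-05, and adjusted p = 0.089 with an estimated correlation), but with library totals only 16 rose and 9 fell (median 0.07). They fell with Torin in 31 of 32 (median -0.72, adjusted p = 1.3e-09, 0.025 with an estimated correlation). Smaller falls were seen with CS alone, in 24 of 32 (median -0.16, adjusted p = 1.2e-05, and adjusted p = 0.060 with an estimated correlation). When CS was added to LPS 24 fell and 5 rose (median -0.20, adjusted p = 0.020, and adjusted p = 0.25 with an estimated correlation). Host genes of small nucleolar RNAs fell with LPS in 13 of 14 cases (median -1.51, adjusted p = 0.025, and adjusted p = 0.29 with an estimated correlation). They rose in 13 of 14 when CS was added to LPS (median 1.34, adjusted p = 0.00069, and adjusted p = 0.091 with an estimated correlation). These 3 lists were written only after the results were seen.

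The test on mRNAs with a 5 prime terminal oligopyrimidine tract was written before its values were seen; the test on small nucleolar RNA host genes and the list of translation factors without the tract were chosen only after. Ribosomal protein mRNAs rose when CS was added to LPS and again with Torin (adjusted p = 0.067 and 0.54 with an estimated correlation), while with CS alone 24 of 76 fell and none rose (adjusted p = 0.48 with an estimated correlation). Stabilisation of mRNAs with this tract when mTOR is inactive is a candidate explanation of the rises. For the rise with CS it would need lower mTOR activity with LPS+CS than with LPS, which was not measured. Torin still changed 10885 genes in LPS+CS cells and lowered 35 of 36 amino acid stress genes. Some target of Torin was thus probably still active there, but no activity was measured. These changes do not tell whether mTOR was less active with LPS+CS than with LPS. The other 15 mRNAs with the tract fell with LPS alone, 12 with 2 rises (median -0.79, adjusted p = 0.021, and adjusted p = 0.22 with an estimated correlation), so a return towards the media level is an alternative for their rise with CS. They had a median of 0.73 for LPS+CS against LPS (14 rose, adjusted p = 3.4e-07, 0.025 with an estimated correlation) and of 0.52 with Torin (14 rose, 1 fell, adjusted p = 0.00014, and adjusted p = 0.061 with an estimated correlation). Translation factors without the tract also rose with CS added to LPS, 9 of 18 with 3 falls (median 0.23, adjusted p = 0.00083, and adjusted p = 0.089 with an estimated correlation), so that rise was not limited to the tract. With Torin 11 of them fell and 4 rose (median -0.27, adjusted p = 0.0031, and adjusted p = 0.11 with an estimated correlation). Both rises may also come from transcription, and mRNA half-lives after transcription is blocked, with and without Torin, would separate the possibilities. Whether CS lowers mTOR activity in cells with LPS could be tested by phosphorylation of its substrates.

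Host genes of small nucleolar RNAs might be part of the amino acid stress response, which also rose with CS added to LPS. With Torin, which lowered that response, their median was 1.07 (8 rose, 2 fell and 4 did not pass the test, adjusted p = 2e-04, and adjusted p = 0.089 with an estimated correlation). A list that follows that response would have fallen, which argues against this only as far as these values go. Many of these transcripts are degraded when translated, so slower translation could be an alternative. With CS alone none of the 14 rose and 1 fell (median -0.03), so it would have to apply only beside LPS; blocking translation in cells with LPS alone would test it.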
